A study of Homo sapiens with 19 samples.

How the data were processed

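Bisulfite sequencing reads were made from genomic DNA of CD14-positive blood monocytes of patients with chronic myelomonocytic leukaemia (CMML), 1 library per patient sample. Bisulfite turns unmethylated cytosine into a base read as thymine and leaves 5-methylcytosine as cytosine, so the share of cytosine reads at a CpG gives its methylation. Per the labels' protocols, mononuclear cells were taken by density centrifugation, the monocytes were enriched by negative magnetic selection, and DNA and RNA were extracted from the same material. Per the submitters' processing notes, the tools were cutadapt, Bismark and methylKit and the genome build was hg19, with no versions or settings given in the sources used here. Whether restriction digestion or capture was used to choose the sequenced part of the genome is not given in the sources used here.

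Each deposited table lists 1 CpG cytosine per row with its position, its strand, a whole-number count of reads (the coverage) and the percent of those reads that showed cytosine and thymine. Per the file headers these are the columns that methylKit writes. No cytosine with under 10 reads was listed in the deposited tables, and cytosine and thymine together made up at least 90% of the reads at every row. The methylated and unmethylated read counts were recovered as the coverage multiplied by each deposited percent and rounded to whole reads. Both strands of a CpG were kept as separate cytosines, as deposited. Duplicate removal and trimming of fragment ends are not described in the sources used here, and PCR copies of a molecule are not independent, so intervals from read counts cover counting error only.

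The sex chromosomes and mitochondrial DNA were left out of all steps. Genes and start sites came from the GENCODE release 44 annotation lifted to GRCh37, the same sequence as hg19 for the autosomes. A promoter was defined as 1500 bp upstream to 500 bp downstream of the annotated start of each autosomal protein-coding gene. Tiles were non-overlapping windows of 1000 bp. The reads of all cytosines in a tile or promoter were summed per library, and a library counted if at least 3 cytosines were covered there. The cytosines summed for a region can therefore differ between libraries. Tiles, promoters and cytosines were tested if at least 7 libraries of each group had a value.

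The 10 libraries labelled as defective in apoptosis were compared with the 9 labelled as non-defective. The patient sample is the replicate, and the replicate numbers were given in accession order, so they pair no libraries. For each region or cytosine, methylated and unmethylated counts were fitted by logistic regression on the group. The fit had an overdispersion factor per region of at least 1 and an F test, which methylKit offers as an option for groups with replicates. P-values were adjusted by the Benjamini-Hochberg method. A call needed an adjusted p under 0.05, a difference of at least 10 percentage points between the means of the libraries and the same sign in the pooled reads. Values with 1 number per library (mean methylation, methylation classes, the CYTL1 promoter, means of gene lists, principal component scores and depth) were compared by a two-sided exact permutation test over all 92378 splits of the 19 libraries, with 95% intervals from inverting that test. The smallest p this test can give is 1.08e-05. Means of gene lists hold only the members with a value in every library, which can be fewer than those tested. The labels name no library batches, so no within-batch values were computed.

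Fixed before the data were examined were the groups, the tests, 21 gene lists, the alternatives and the rule for naming. Named are CYTL1, the called tiles or, with none called, the 5 tiles with the smallest p in each direction, the called promoters, and the members of each list that passed the test adjusted over the list alone or, with none, the 2 with the smallest p. Some items that this rule names are not reported here. Other genes were chosen after their values were seen, and the text says so. The lists cover the gene in the series title, the BCL2 family, death receptors and caspases, the MAPK pathway, cytokines and chemokines, cytokine receptors, inflammasome and NF-kB genes, interferon response genes, monocyte and nonclassical monocyte genes, T cell, B cell, NK cell, granulocyte and progenitor genes, HOX genes, developmental transcription factors, tumour suppressors of myeloid neoplasms, genes mutated in CMML with epigenetic enzymes, imprinted genes and housekeeping genes.

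The alternatives were a coverage minimum of 20 reads, removal of the 0.1% of cytosines with the highest coverage in each library, regions covered in all 19 libraries, at least 5 cytosines per region, tiles of 500 bp, promoters of 500 bp on either side of the start, stricter and looser thresholds, class bounds of 10% and 90%, tiles scaled to unit variance or the 10% most variable tiles for the components, other ways of averaging for mean methylation, the CYTL1 promoter and the lists, and leaving out each library in turn. Limma was run on logit-transformed values with an offset of 1 read, with and without the library mean as covariate, and on region medians with an offset of 0.01. Leaving out the 3 libraries with the most bases other than cytosine and thymine, and the counts at an unadjusted p under 0.05, were added after seeing the data.

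The logistic test, the permutation test and limma were tested on simulated data. A simulation of all 114219 tested tiles used the real coverage and changed only tiles of intermediate mean methylation. Its spread between libraries was estimated with counting error included, and counting error was then drawn again, which widens it. Recovery at nearly unmethylated or nearly fully methylated tiles was not simulated. With few changed tiles (66 or 67 of each size), the logistic test with adjustment had 0 false calls. It recovered 0% of the tiles changed by 10 points, 4.48% of those changed by 20 points and 13.6% of those changed by 30 points. With 1089 changed tiles of each size it recovered 1.93%, 15.9% and 37.01%, with 40 false calls (6.28% of the calls). With few changed tiles, at an unadjusted p under 0.05 it recovered 32.8%, 65.7% and 84.8%, while 8.58% of the unchanged tiles also fell under that value. No pair among the 171 pairs of libraries agreed within sampling noise over 90160 tiles: the mean chi-square per tile was at least 13.0, against 1 for repeated sampling of 1 library, so no library was counted more than once. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3 and limma 3.58.1 were used.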

Results

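CpG methylation was measured in monocytes of patients with CMML, a clonal blood cancer in which monocytes accumulate. Monocytes are the blood phagocytes marked by CD14. The labels divide the samples into 10 whose monocytes had defective apoptosis and 9 whose monocytes did not, without saying how apoptosis was scored. The series title names cytokine-like protein 1 (CYTL1), a secreted protein, together with the survival protein MCL1 and the MAPK pathway. The comparison asks where methylation differs between monocytes with defective and non-defective apoptosis. Each library covered between 1700086 and 3350758 autosomal CpG cytosines with at least 10 reads, at a mean of 47.0 to 125.9 reads per cytosine. Coverage did not separate the groups, with 77.5 ± 20.3 reads per cytosine in defective libraries (SD, n = 10) and 81.1 ± 16.4 in non-defective libraries (SD, n = 9; exact permutation p = 0.680). Of 5360747 cytosines seen in any library, 1107236 were covered in all 19.

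The monocyte methylomes of both groups had the same overall shape, with unmethylated CpG-dense regions and methylated CpG-poor ones. Over the cytosines covered in all libraries, mean methylation was 34.1% ± 0.545 in defective libraries (SD, n = 10) and 33.4% ± 1.88 in non-defective libraries (SD, n = 9). The difference of 0.690 points was within the spread between libraries (95% interval -0.317 to 1.95, exact permutation p = 0.319). Its sign turned to -0.0283 points over all cytosines of each library and to -0.0772 points as methylated over all reads. Cytosines under 20% methylation made up 61.4% ± 0.864 of the cytosines in defective and 61.5% ± 0.781 in non-defective libraries. Cytosines at 80% or more made up 29.9% ± 0.593 and 29.1% ± 4.10. Tiles with 3 to 9 covered cytosines had a mean of 76.8% in defective and 75.02% in non-defective libraries, and tiles with 50 or more had 4.91% and 4.97%. None of these 7 classes differed between the groups, with adjusted exact permutation p-values from 0.814 to 0.883. A single non-defective library lay apart at 28.5%, and without it the difference in mean methylation was 0.0856 points (exact permutation p = 0.735).

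**Figure D1:**
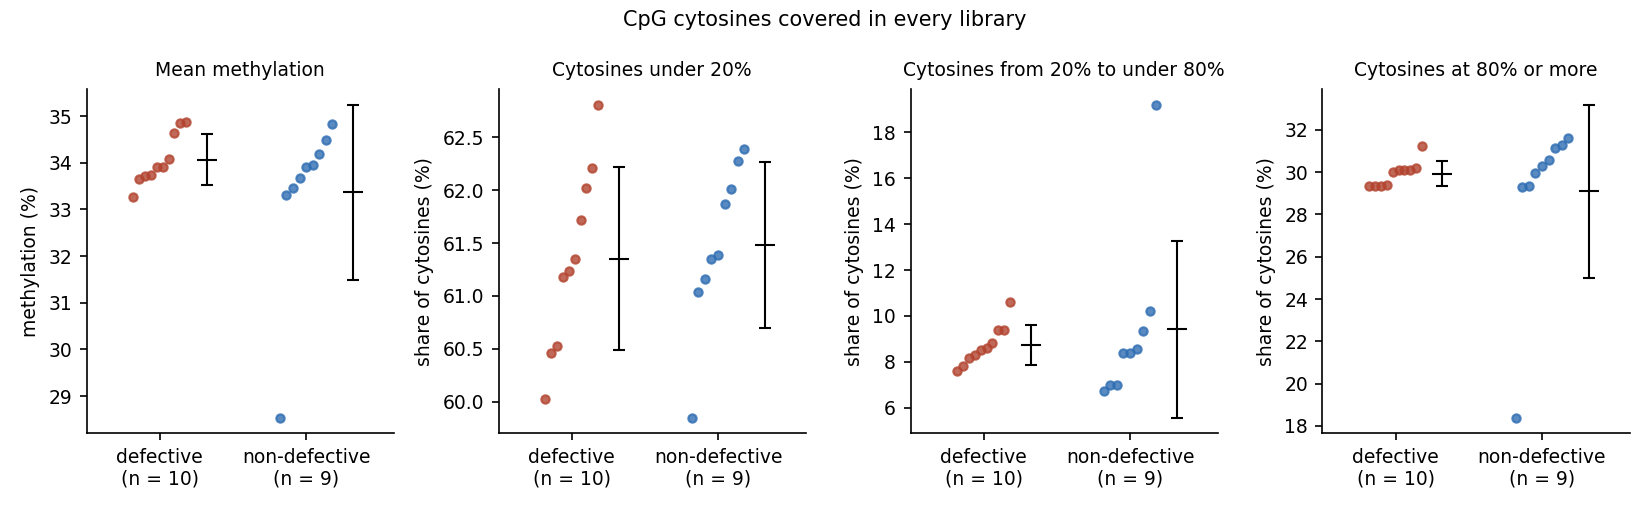
Mean methylation and the shares of cytosines in 3 methylation classes, in percent, over the 1107236 cytosines covered in every library; each point is 1 library and bars give mean ± SD of 10 defective and 9 non-defective libraries. The groups overlap in all 4 panels, and a non-defective library at 28.5% mean methylation stands apart.

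The CYTL1 promoter was highly methylated in the monocytes of both groups. The gene lies on the minus strand of chromosome 4 from 5016313 to 5021185 in hg19, and its promoter window runs from 5020685 to 5022685 (ENSG00000170891.11_10). Methylation was 84.6% ± 11.3 in defective libraries (SD, n = 10) and 87.1% ± 11.1 in non-defective libraries (SD, n = 9), on 195 to 737 reads and 4 to 10 cytosines per library. The difference of -2.54 points was smaller than the spread between libraries (95% interval -13.2 to 8.36, exact permutation p = 0.626), and single libraries ranged from 60.6% to 100%. The sign of this difference turned to 0.0552 points when cytosines were averaged in place of reads (exact permutation p = 0.995), and to 1.67 points without the 3 defective libraries with the most other bases (exact permutation p = 0.767). It was widest, at -5.86 points, without non-defective replicate 4, the library at 60.6%. With any 1 library left out the exact permutation p was at least 0.197. The 4 cytosines of the window covered in every library lie between 5021703 and 5021779, 518 to 594 bp upstream of the start site. At 5021703 methylation was 91.5% ± 11.2 in defective and 82.0% ± 19.97 in non-defective libraries, and at 5021779 it was 89.6% ± 11.3 and 95.8% ± 6.18. Beyond the 3' end of the gene, the cytosine at 5015993 was at 24.4% ± 27.4 and 23.8% ± 25.3. None of the 6 cytosines around the gene differed between the groups (adjusted exact permutation p of at least 0.439). In 4 libraries only could a value be had for the window within 500 bp of the start site, so methylation at the start site itself was not compared.

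**Figure D2:**
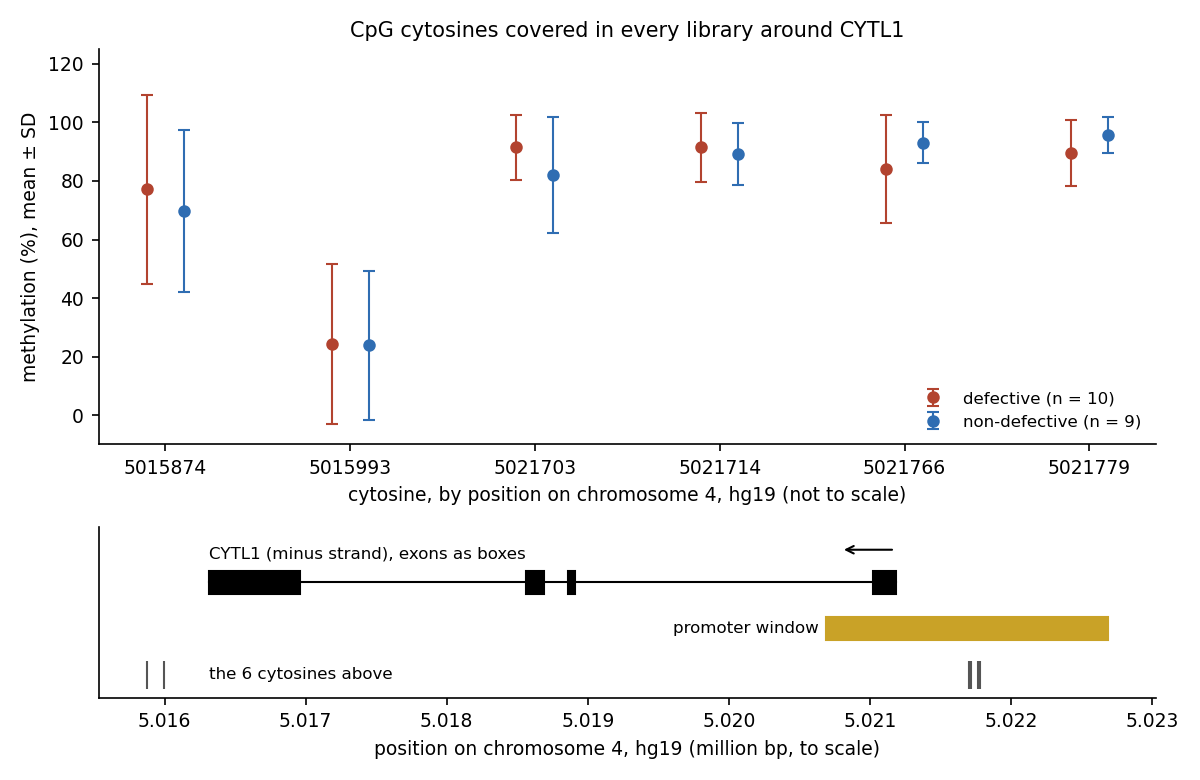
Methylation in percent, as mean ± SD of 10 defective and 9 non-defective libraries, at the 6 cytosines around CYTL1 covered in every library (top), and their place on a map of the gene in hg19 (bottom). The 4 cytosines upstream of the gene have group means between 82.0% and 95.8%, and the error bars of the groups overlap at every cytosine.

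No tile of 1000 bp passed the test between defective and non-defective monocytes. Of 114219 tiles tested by the overdispersed logistic model, 0 were called, and the smallest adjusted p was 0.507. At an unadjusted p under 0.05 there were 8247 tiles (7.22%), 5024 higher and 3223 lower in defective libraries. Limma on logit values also called 0 tiles, with 6798 under that value. Limma on the medians of tiles called 11, all higher in defective libraries, where their mean lay between 98.1% and 99.8%. A tile between genes on chromosome 13 (57545001 to 57546000) was called with a minimum of 20 reads (99.7% against 85.1%, adjusted p = 0.0292) and without defective replicate 4 (adjusted p = 0.0409). In simulation, where only tiles of intermediate methylation were changed, 13.6% of those changed by 30 points were recovered after adjustment with few changed tiles. With many changed tiles it was 37.01%, with 40 false calls. Recovery at nearly unmethylated or nearly fully methylated tiles was not simulated.

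The tile with the widest gap among those with the smallest p lies in an intron of ERICH1 on chromosome 8 (602001 to 603000). It was at 86.4% ± 19.8 in defective libraries (SD, n = 10) and 46.8% ± 24.7 in non-defective libraries (SD, n = 9), on 46 to 1098 reads (adjusted p = 0.507, unadjusted exact permutation p = 0.00236). Of the other tiles with the smallest p for a higher value in defective libraries, 3 were nearly fully methylated there. These lie in introns of RALY (chromosome 20, 32616001 to 32617000, 99.8% against 94.0%), a gene for an RNA-binding protein, and of TMEM117 (chromosome 12, 44702001 to 44703000, 100% against 97.6%), and between genes on chromosome 18 (76011001 to 76012000, 99.3% against 93.8%). Of the tiles with the smallest p for a lower value, 3 were at 86.2% to 87.8% in defective and 94.1% to 95.3% in non-defective libraries: between genes on chromosome 7 (155967001 to 155968000), in an exon of the long non-coding gene ENSG00000231178 on chromosome 6 (159796001 to 159797000) and between genes on chromosome 14 (71041001 to 71042000). The remaining 2 were almost unmethylated, near the start of RPS19BP1 on chromosome 22 (39931001 to 39932000, 0% against 2.62%) and in an intron of SLC45A3 on chromosome 1 (205648001 to 205649000, 0.0108% against 1.06%). With limma on tile medians the difference was 1.47 points for the RALY tile, 0.229 for TMEM117, 2.003 on chromosome 18 and -1.502 on chromosome 7, and 0 for RPS19BP1 and SLC45A3. Without the 3 defective libraries with the most other bases it was -4.91 points on chromosome 14.

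Single CpG cytosines gave 11 calls among 1570834 tested, 10 higher and 1 lower in defective libraries. All 11 were chosen by the call itself and not by the rule for naming. The largest difference was the lower one, in coding sequence of OLIG3, a neural transcription factor gene, at position 137815226 on chromosome 6, with 0.224% in defective and 29.0% in non-defective libraries (adjusted p = 0.0351). Of the higher ones, a cytosine in coding sequence of PIK3CD, which encodes the leukocyte PI3-kinase subunit delta, at 9775994 on chromosome 1 was at 100% against 85.9%. Cytosines in introns of RNF168 (chromosome 3, 196218409), NIBAN2 (chromosome 9, 130313263) and LRRC27 (chromosome 10, 134170252) were at 99.6% against 80.02%, 99.87% against 77.0% and 100% against 82.5%. In each of the 11, 1 group lay at 99% or more or at 1% or less. Limma on logit values called only the OLIG3 cytosine (adjusted p = 0.0160). Of the tested neighbours of that cytosine within 100 bp, 0 of 4 differed alike. The same held for 7 of 9 at PIK3CD, 3 of 6 at NIBAN2 and 0 of 2 at each of RNF168 and LRRC27. The count moved with single libraries. It was 0 without defective replicate 2 or 10, 1 without defective replicate 5 and 3 to 6 without defective replicate 1, 3, 4, 6, 7 or 8. Without any 1 of the 9 non-defective libraries it was 16 to 26. Without the 3 defective libraries with the most other bases it was 0, with 78727 cytosines at an unadjusted p under 0.05 against 128521 with all libraries.

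Most promoters of the genes that run apoptosis and its MAPK control were unmethylated in the monocytes of both groups. Of 14595 promoters tested, 12404 (85.0%) had a mean under 10% over all libraries and 654 (4.48%) were at 80% or more. The logistic model called 0 promoters, with 1278 at an unadjusted p under 0.05, of which 474 were higher and 804 lower in defective libraries. Limma called 0 as well, with 626 under that value. In the BCL2 family, 16 of 17 tested promoters lay under 10%, and BCL2A1, for a survival protein, was at 88.8% ± 7.61 in defective and 86.3% ± 10.2 in non-defective libraries. The mean of the family was 1.16% ± 0.509 in defective and 1.298% ± 0.637 in non-defective libraries. This mean is over the 16 members covered in all libraries and leaves out BCL2A1. MCL1, chosen because the series title names it, was at 0.0936% ± 0.0869 (SD, n = 10) and 0.0550% ± 0.0560 (SD, n = 9). BAK1, which encodes a pore-forming executor of mitochondrial apoptosis, was the sole member of the family to pass adjusted over the list alone (adjusted p = 0.0411, and 0.555 over all promoters). Its promoter on chromosome 6 (33547553 to 33549553) was at 0.0175% ± 0.0413 in defective libraries (SD, n = 10) and 1.71% ± 3.37 in non-defective libraries (SD, n = 9; exact permutation p = 0.0156), on 509 to 2636 reads. Without non-defective replicate 1, which was at 10.3%, the difference went from -1.69 to -0.624 points (adjusted p over the list alone = 0.113). That library covered the most cytosines, 3350758. Its promoter values can rest on cytosines that other libraries lack, which was not tested. The difference was -1.18 points with a minimum of 20 reads (adjusted p over the list alone = 0.143), -0.0707 within 500 bp of the start site (0.349) and 0 with limma on medians (0.356). Without any 1 of the 10 defective libraries it stayed between -1.69 and -1.71 points while the adjusted p over the list alone lay between 0.0632 and 0.0976, and limma on logit values gave 0.469.

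Death receptor and caspase promoters had a mean of 1.504% ± 0.412 in defective and 1.37% ± 0.316 in non-defective libraries, and 0 of 20 tested members passed adjusted over the list alone. CYCS, for cytochrome c, was at 0.0353% against 0.248%, a difference of -0.212 points that was -0.0272 without non-defective replicate 1. In the MAPK pathway 0 of 29 members passed, and the list mean was 1.07% ± 0.136 and 1.09% ± 0.2004. MAPK8, for the stress kinase JNK1, was at 1.49% ± 0.662 and 2.29% ± 1.19, and SPRY2, for an inhibitor of the pathway, at 0.199% ± 0.284 and 0.0581% ± 0.05004. The SPRY2 difference of 0.141 points was 0.0566 without defective replicate 3. Among 12 cytokine and chemokine promoters 0 passed, and the list mean was 3.55% and 3.51%. CXCL2 was at 1.09% against 0.0843%, a difference of 1.01 points that was 0.140 without defective replicate 10 and 0.198 without the 3 libraries with the most other bases, and OSM was at 0.0464% against 0.0804%, a difference of -0.0340 points that was -0.00616 without non-defective replicate 1 and -0.0588 within 500 bp of the start site. Of 10 cytokine receptor promoters, with a mean of 9.96% and 9.81%, 0 passed. CXCR4 was at 0% against 0.144% and passed over the list alone without non-defective replicate 5 (difference -0.0488 points, adjusted p = 0.0207), with -0.0674 points within 500 bp of the start site and 0 with limma on medians, and CSF2RB, for the shared beta chain of the GM-CSF receptor, was methylated in both groups at 93.0% ± 5.93 and 90.2% ± 5.27. The CSF2RB difference of 2.79 points was 1.66 without non-defective replicate 1 and 0.245 with limma on medians. Inflammasome and NF-kB promoters (0 of 15 passed) averaged 6.90% and 6.91%, with IRAK1BP1 at 0.0553% against 0.147%, a difference of -0.0917 points that was -0.0576 without non-defective replicate 9. For RELA the values were also under 1% in both groups. Interferon response promoters (0 of 8 passed) averaged 18.1% ± 1.67 and 17.2% ± 3.23, with PARP9 at 1.19% against 1.89% and OAS3 at 0.0216% against 0.925%. The OAS3 difference was 0.0216 points, with the opposite sign, without non-defective replicate 1, and 0.01005 within 500 bp of the start site. That of PARP9 went from -0.699 to -0.449 points without non-defective replicate 9 and to -0.246 within 500 bp of the start site.

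The monocyte identity list had the smallest p of the gene lists, which did not pass adjustment over the 21 lists, and its gap was mostly that of 1 member, TYROBP. The mean over 7 promoters was 8.28% ± 2.33 in defective libraries (SD, n = 10) and 5.06% ± 2.71 in non-defective libraries (SD, n = 9), a difference of 3.22 points (95% interval 0.766 to 5.66, exact permutation p = 0.0140, adjusted p = 0.295). With a minimum of 20 reads the difference was 0.150 points (adjusted p = 0.927). That mean holds only the promoters covered in all libraries at this minimum, so its members can differ. TYROBP taken alone still differed by 18.8 points there. The median difference over the 8 tested members was 0.140 points. TYROBP, the adaptor of activating myeloid receptors, had the widest gap in the list, at 21.6 points. Its promoter on chromosome 19 (36398697 to 36400697), with 3 covered cytosines and 151 to 1392 reads per library, was at 50.2% ± 16.6 in defective libraries (SD, n = 10) and 28.6% ± 19.9 in non-defective libraries (SD, n = 9; unadjusted exact permutation p = 0.0214). It did not pass adjusted over the list alone (adjusted p = 0.0711). Without non-defective replicate 2 or non-defective replicate 8 it did, at 25.3 points (adjusted p = 0.0165) and 25.2 points (adjusted p = 0.0280). Without any other single library the adjusted p over the list alone was above 0.05, and it was highest without non-defective replicate 1, at 0.362 (19.3 points). The CD14 promoter, chosen after its values were seen, was unmethylated at 0.638% and 0.513%. Promoters of nonclassical monocyte genes averaged 15.1% ± 1.14 and 13.5% ± 1.88, a difference of 1.601 points (exact permutation p = 0.0315, adjusted p = 0.330). LYPD2 in this list (chromosome 8, 143833450 to 143835450) was at 95.6% ± 1.95 and 87.1% ± 11.2, a difference of 8.502 points that was 5.55 without non-defective replicate 4 and 4.61 with limma on medians, and TCF7L2 was under 1% in both groups.

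**Figure D3:**
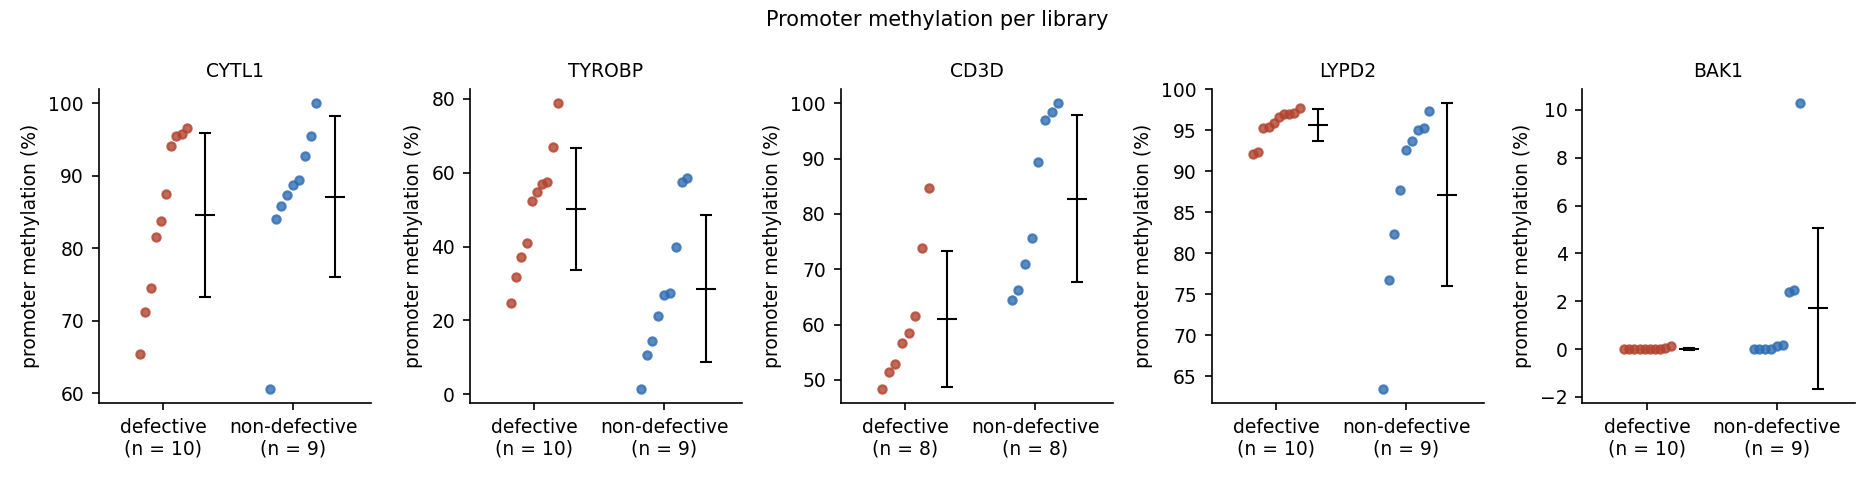
Promoter methylation in percent of CYTL1, TYROBP, CD3D, LYPD2 and BAK1; each point is 1 library and bars give mean ± SD per group, with 10 defective and 9 non-defective libraries except for CD3D with 8 and 8. TYROBP averages 50.2% and 28.6% with overlapping libraries, and the BAK1 mean of 1.71% in non-defective libraries includes a library at 10.3%.

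Genes of other blood cells served as markers of what else the monocyte fraction could hold. Only a promoter methylated in most cells of the fraction could show other cells by a lower value. Under 10% lay 11 of 11 tested progenitor promoters, 3 of 4 for B cells, 3 of 9 for T cells and 2 of 6 for granulocytes. The lack of a difference at these says nothing about cell content. T cell promoters averaged 31.5% ± 3.24 in defective and 29.2% ± 3.81 in non-defective libraries (exact permutation p = 0.174). This mean is over the 7 covered in all libraries and leaves out CD3D and CD3G. Of 9 tested, 0 passed adjusted over the list alone. B cell promoters averaged 6.14% ± 5.05 and 4.91% ± 2.81 (exact permutation p = 0.530). CD3D and CD3G, neighbouring genes of the T cell receptor complex on chromosome 11, share their 3 covered cytosines. CD3D (118212920 to 118214920) was at 61.0% ± 12.3 in 8 defective libraries and 82.8% ± 15.1 in 8 non-defective libraries (unadjusted exact permutation p = 0.00963), on 94 to 457 reads, with an adjusted p over the list alone of 0.0603. Leaving out any of 4 single libraries brought that value under 0.05 (non-defective replicates 2, 5 and 9 and defective replicate 10), with differences of -22.8 to -25.2 points, and it was highest without non-defective replicate 1, at 0.134 (-19.5 points). With limma on promoter medians the difference was -2.98 points for CD3D and -3.67 for CD3G (adjusted p over the list alone = 0.641). With limma on logit values both passed adjusted over the list alone (adjusted p = 0.0431), with coefficients on the logit scale of -2.59 for CD3D and -2.601 for CD3G. Of B cell promoters 0 of 4 passed, with TNFRSF13C, for the BAFF receptor, at 0.960% against 1.55% and an adjusted p over the list alone of 0.0501, which came under 0.05 without defective replicate 7, 8 or 9 or non-defective replicate 4, 5, 6 or 8, at differences of -0.653 to -0.703 points. Without non-defective replicate 1 that value was 0.255 (-0.429 points), and with limma on logit values it was 0.330. Its difference was -0.345 points with a minimum of 20 reads, 0 with limma on medians and 0.0681, with the opposite sign, within 500 bp of the start site. CR2 was at 0.462% against 0.321%, a difference of 0.141 points that was 0.0690 without defective replicate 10, 0.0854 without defective replicate 7 and 0.228 without non-defective replicate 4. The sole NK cell promoter with a value, NCR1, was at 81.8% ± 11.8 and 80.3% ± 12.7. Granulocyte promoters (0 of 6 passed) averaged 14.2% ± 4.20 and 12.496% ± 5.88, with CSF3R, for the G-CSF receptor, at 1.76% against 0.249% and LTF, for lactoferrin, at 18.5% against 10.8%. The CSF3R difference of 1.51 points was 0.564 without defective replicate 3, and the LTF difference of 7.69 points was 5.02 without defective replicate 4, 11.6 with limma on medians and 2.83 without the 3 defective libraries with the most other bases. Progenitor promoters (0 of 11 passed) averaged 1.39% ± 0.979 and 1.86% ± 1.81. CRHBP in that list (chromosome 5, 76247370 to 76249370) was at 0.969% ± 1.55 and 5.82% ± 7.40, with an adjusted p over the list alone of 0.0593. That value came under 0.05 without defective replicate 2 or 4, or non-defective replicate 2, 3, 6 or 8. The differences were then -4.75 to -5.58 points. With promoters of 500 bp on either side the adjusted p over the list alone was 0.0431, but the difference was the same, -4.86 points. This adjustment also depends on how many members are tested in that window, so it adds no evidence for CRHBP. Without non-defective replicate 5 the difference was -3.16 points (adjusted p over the list alone = 0.106), and without non-defective replicate 1 it was -3.58 points (0.502). The adjusted p over the list alone was also 0.409 with limma on logit values, 0.545 with the library mean as covariate and 0.364 with limma on medians, where the difference was -1.92 points. KIT, for the stem cell factor receptor, was at 0.937% against 4.77%, a difference of -3.84 points that was -0.683 without non-defective replicate 5 and 0.0377, with the opposite sign, within 500 bp of the start site.

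Among developmental and leukaemia genes, HOX promoters had a list mean of 13.0% ± 2.24 and 13.4% ± 2.66. Of the 37 tested, 21 lay under 10% and 3 were at 50% or more, and 0 passed. HOXB4 was at 0.230% against 0.0768%, a difference of 0.153 points that was 0.0882 without defective replicate 10 and 0.0303 without the 3 libraries with the most other bases, and HOXA13 at 0.291% against 0.466%, a difference of -0.175 points that was -0.113 without non-defective replicate 8. Developmental transcription factor promoters averaged 6.17% ± 1.96 and 6.32% ± 3.41, with 0 of 84 passing. FOXA1 was at 1.48% ± 1.14 against 0.548% ± 0.345, a difference of 0.927 points that was 0.593 within 500 bp of the start site and 0.572 without the 3 defective libraries with the most other bases. Promoters of tumour suppressors of myeloid neoplasms averaged 3.95% ± 1.11 and 4.45% ± 2.04, with 0 of 28 passing. IGF2, which that list holds, was at 1.25% ± 0.448 against 2.29% ± 1.02, a difference of -1.04 points that was -0.599 within 500 bp of the start site, and RASSF1 at 0.0558% against 0.189%, a difference of -0.133 points that was -0.0664 without non-defective replicate 8. Genes mutated in CMML and epigenetic enzyme genes were unmethylated, with a mean of 0.403% ± 0.192 and 0.388% ± 0.135 and 0 of 22 passing. CBL, for a ubiquitin ligase that restrains growth factor receptors, was at 0.0379% against 0.133%, with an adjusted p over the list alone of 0.0834 that came under 0.05 without non-defective replicate 2, 7, 8 or 9, at differences of -0.104 to -0.111 points, and with a minimum of 20 reads, at -0.105 points (adjusted p over the list alone = 0.0456). The same value was 0.507 without non-defective replicate 1, 0.964 with limma on logit values, 0.952 with the library mean as covariate and 0.304 with limma on medians, where the difference was 0. UHRF1, needed for maintenance of methylation, was at 0.167% against 0.573%, a difference of -0.406 points that was -0.180 without non-defective replicate 8 and -0.202 within 500 bp of the start site. Imprinted genes averaged 21.9% ± 4.42 and 21.7% ± 2.87 with 0 of 13 passing, and PEG10 was at 4.36% ± 6.56 against 1.07% ± 1.201, a difference of 3.29 points that was 1.51 without defective replicate 1, 1.17 with limma on medians and 1.87 without the 3 libraries with the most other bases, and BLCAP at 0.406% against 0.134%, a difference of 0.272 points that was 0.0161 without defective replicate 10, 0.102 within 500 bp of the start site and -0.0103, with the opposite sign, without the 3 libraries. Housekeeping promoters averaged 2.36% ± 0.320 and 2.23% ± 0.190 with 0 of 24 passing, and both SDHA and TFRC were under 0.1%. The mean of none of the 21 lists differed between the groups after adjustment, with adjusted exact permutation p-values from 0.295 to 0.978.

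**Figure D4:**
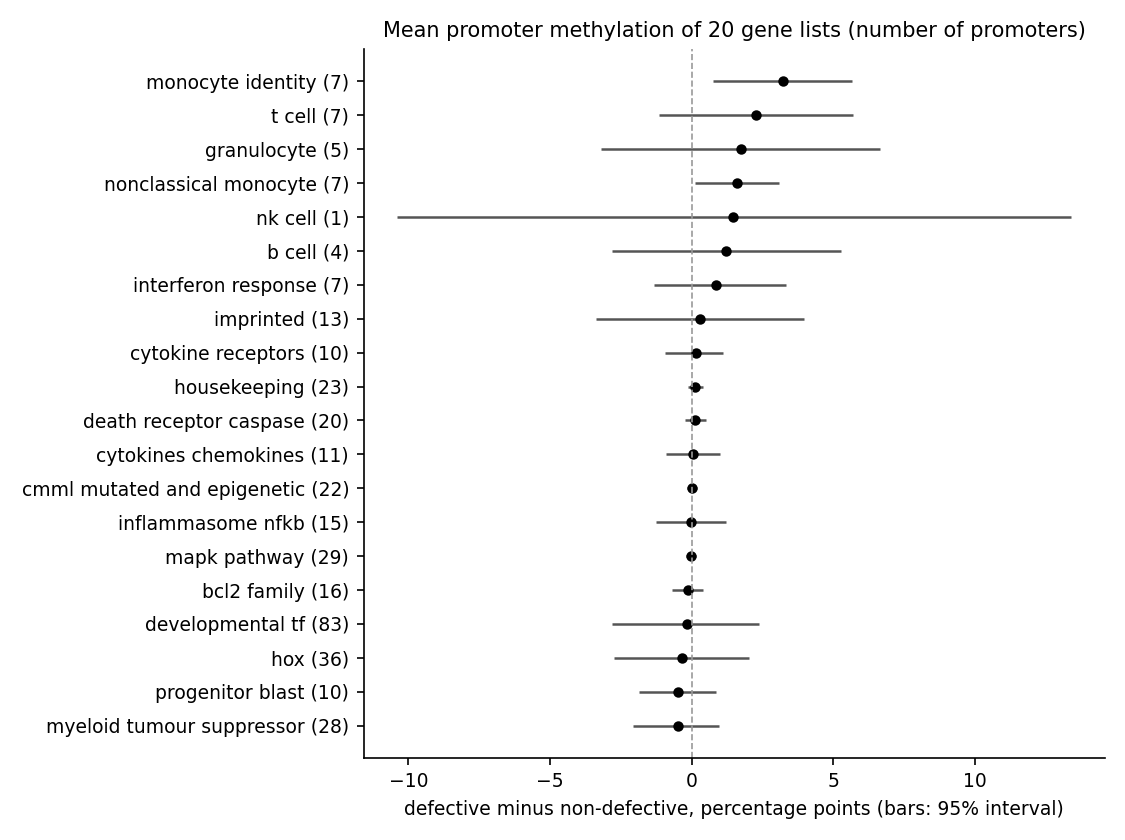
Difference in mean promoter methylation between defective and non-defective libraries, in percentage points with 95% intervals from the exact permutation test, for 20 gene lists with the number of promoters in brackets. The intervals of the monocyte identity and nonclassical monocyte lists lie above 0 before adjustment, and all other intervals include 0.

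The main axes of variation between the monocyte methylomes did not follow apoptosis. Over 90160 tiles covered in all 19 libraries, the first 3 principal components held 22.2%, 10.8% and 6.77% of the variance. Their scores did not differ between defective and non-defective libraries (exact permutation p = 0.145, 0.645 and 0.119, adjusted p of at least 0.218). The non-defective library with low methylation alone gave 87.0% of the squared scores of the first component.

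A technical measure differed between the groups by an amount that did not pass its test. The share of cytosines where some reads showed a base other than cytosine or thymine was 3.13% ± 1.01 in defective libraries (SD, n = 10) and 2.36% ± 0.432 in non-defective libraries (SD, n = 9; exact permutation p = 0.0519, adjusted p over 4 depth measures = 0.208). The 3 libraries with the highest shares, 4.41% to 4.59%, were all defective, and without them the logistic model called 0 cytosines, 0 tiles and 0 promoters, with 5019 tiles and 897 promoters at an unadjusted p under 0.05.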

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

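Of the tests in this part, those of donor variants, T cells, reads per promoter and a batch were chosen after the result was seen. A library was picked out when its gap to the nearest other library of its group was large for the range of the group (Dixon's 95% value). For normally distributed values chance picks out about 1 in 20 groups. Many promoters here are almost unmethylated in most libraries, where a single higher library is picked out more readily, so this rate does not hold for them.

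A single library, non-defective replicate 4, stood apart in 6 measures of overall methylation. Its mean methylation was 28.5%, with 33.3% in the next library, and its share of cytosines at 80% or more was 18.4%. Its share from 20% to under 80% was 19.2%, its tiles with 3 to 9 cytosines averaged 62.2% and those with 10 to 19 averaged 45.9%, and its score on the first component was 0.933. Among non-defective libraries it was also the lowest for the interferon response list at 9.19% and for the CYTL1 promoter at 60.6% (528 reads, 95% Wilson interval 56.4 to 64.7), and the highest for the promoter of CR2 at 1.02%.

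The lower methylation of this library was weighed against its chemistry and depth, and no biological explanation was tested, since the labels separate it from its group by nothing. Fewer reads at methylated cytosines were argued against: at cytosines with a mean of 80% or more elsewhere, the gap was 16.4 points at 10 reads and 16.6 points at 50 reads (101% of it). Over all cytosines the gap at 50 reads was 38.4% of that at 10 reads, which met the bound written for few reads as the cause, but the cytosines with 50 reads are another mix (median of the other libraries 14.7% against 33.9%), so that test was set aside after its result was seen. Uniform over-conversion of methylated cytosines stays open: 25.9% of 5648 tiles at 90% or more in every other library stayed there, between the bounds of 10% and 30% written beforehand. The median of these tiles was 83.4% in this library and 96.2% in the others. Their loss was uneven, with a 10th percentile of 66.3% and a 90th percentile of 95.4% in this library. Tiles at 5% or less in every other library had a median of 0.0305% in it and 0.0553% in the others.

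Single cytosines were called while no tile or promoter was. Of 100 splits of the 19 libraries, the real one included, 3 gave at least the 11 called cytosines of the real groups. The highest other split gave 19, and 41 of the 99 others called at least 1. The share lay under the bound of 0.05 written for chance, but it was not adjusted for the other counts compared over the splits. Chance is therefore not excluded for the count or for any single cytosine. An inflated F statistic from a group with no spread is a candidate explanation: all 11 had a group mean at 99% or more or at 1% or less, and limma on logit values called 9.09% of them. Sequence variants of donors cannot be told apart from methylation here, since 36.4% of the called cytosines (4 of 11, with 8 having any neighbour within 100 bp) had a neighbour that differed alike, between the bounds of the test. The apoptosis classes of the design stay among the open explanations, untested.

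CD3D and CD3G promoters had lower and the TYROBP promoter higher values in defective libraries, none of which passed adjustment. CD7, ZAP70 and LAT, the other T cell promoters at 30% or more in non-defective libraries, had a median difference of 3.01 points (range 0.778 to 6.66). They gave no sign of T cells left after the negative selection. Whether these promoters are less methylated in T cells than in monocytes was not measured, so T cells are not excluded. Few reads stay open: the spread between libraries was at least 3.94 times the binomial one, but separate patients would give such a ratio in any case, and with limma on promoter medians the CD3D difference was -2.98 points while that of TYROBP was 28.2 points, with 18.8 points for TYROBP with a minimum of 20 reads. A batch marked by the 3 libraries with the most other bases is argued against for TYROBP, since without them its difference kept 93.5% of its size (20.2 points). That of CD3D was then -27.9 points, but on fewer defective libraries than the minimum of 7 for a test. Other cell mixtures, batches the labels do not name, chance and the apoptosis classes stay open, untested.

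Among measures of depth, given in units of 1000000, non-defective replicate 1 had the most cytosines at 3.35 units and the most reads over cytosines at 379.9 units. Defective replicate 10 had the highest mean coverage of its group at 125.9 reads, and the most reads over cytosines of its group at 271.8 units. Defective replicate 9 had the highest share of cytosines at 80% or more in its group at 31.2%. Non-defective replicate 3 was highest in its group for tiles with 50 or more cytosines at 6.66%, for the developmental transcription factor list at 13.9% and for the tumour suppressor list at 9.24%.

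Among the named tiles, the ERICH1 tile was at 33.1% in defective replicate 7 (127 reads, 95% Wilson interval 25.5 to 41.6) with 79.3% in the next library. The RALY tile was at 98.5% in defective replicate 8 and the SLC45A3 tile at 0.0968% in defective replicate 10.

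Among promoters in non-defective libraries, replicate 1 was the highest for BAK1 at 10.3% (2636 reads, 95% Wilson interval 9.18 to 11.5), CYCS at 1.73%, OSM at 0.303% and OAS3 at 8.33%. Replicate 5 was the highest for KIT at 29.996% (2387 reads), CXCR4 at 0.902% and the cytokine receptor list at 13.2%. Replicate 2 was the highest for the B cell list at 10.999% and CSF3R at 1.62%, and replicate 9 for CXCL2 at 0.275%.

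Among promoters in defective libraries, replicate 10 was the highest for CXCL2 at 8.90% (3282 reads, 95% Wilson interval 7.97 to 9.92), RELA at 0.250%, OAS3 at 0.216%, BLCAP at 2.71% and the nonclassical monocyte list at 17.8%. Replicate 3 was the highest for CSF3R at 10.3% (390 reads, 95% Wilson interval 7.62 to 13.7), SPRY2 at 0.961%, HOXA13 at 0.637% and the BCL2 family list at 2.33%. Replicate 8 was the highest for BAK1 at 0.127%, and replicate 9 for TCF7L2 at 0.275%.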

How the results depend on the processing

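Leaving out the 3 libraries with the most other bases and the counts at an unadjusted p under 0.05 were chosen after seeing the data. No promoter was called by the logistic model or by limma under any of 30 alternatives, while between 163 (limma on region medians) and 1424 promoters (without non-defective replicate 2) lay under an unadjusted p of 0.05. With limma on region medians the difference was 0 for 26 of the 34 promoters named from the lists that had this value. No class of methylation, list mean or principal component passed its test under the alternatives run for it. The count of called tiles was 0 except for 11 with limma on region medians and 1 with a minimum of 20 reads, and it ranged from 0 to 1 with 1 library left out. The count of called cytosines, 11, went to 0 with an adjusted p under 0.01 and 25 points, 40 with no minimum difference, 1 with limma on logit values, 2 with limma and the library mean as covariate and 0 without the 3 libraries with the most other bases, and ranged from 0 to 26 with 1 library left out. Mean methylation differed by -0.0283 points over all cytosines of each library and by -0.0772 points as methylated over all reads, and by 0.0856 to 0.877 points with 1 library left out. The CYTL1 promoter differed by 0.0552 points as a mean over cytosines and by 1.67 points without the 3 libraries, and by -5.86 to -0.415 points with 1 library left out. The 500 bp promoter of CYTL1 was not run, since 4 libraries only had a value. Apart from the smaller sets of libraries, cytosines or tiles that an alternative itself makes, the cause of these changes was not tested.

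Lists whose difference turned sign did so around 0, with exact permutation p-values adjusted over the lists of 0.528 or more. With promoters of 500 bp on either side, the differences were 0.0480 points for the BCL2 family, -0.164 for cytokines and chemokines, -0.0829 for interferon response, -0.01001 for CMML and epigenetic genes and -0.0275 for housekeeping genes. OAS3 was then at 0.01005, TNFRSF13C at 0.0681 and KIT at 0.0377 points. CMML and epigenetic genes differed by -0.00322 points after subtracting the mean of all promoters and by -0.00594 with a minimum of 20 reads. Without the 3 libraries, the differences were 0.0321 points for the MAPK pathway, -0.269 for cytokines and chemokines, -0.687 for B cell genes and -0.0103 for BLCAP.

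With 1 library left out, the differences ranged from -0.267 to 0.0389 points for the BCL2 family, -0.0587 to 0.0135 for the MAPK pathway, -0.125 to 0.290 for cytokines and chemokines, -0.0431 to 0.574 for cytokine receptors, -0.291 to 0.285 for inflammasome and NF-kB genes and -0.128 to 1.21 for interferon response. They ranged from -1.63 to 3.73 for NK cell genes, -0.713 to 0.0218 for progenitor genes, -0.687 to 0.229 for HOX genes, -0.595 to 0.795 for developmental transcription factors and -0.725 to 0.105 for tumour suppressors. For CMML and epigenetic genes the range was -0.0263 to 0.0394, for imprinted genes -0.561 to 0.939 and for OAS3 -1.02 to 0.0216. Depth limits what is compared: 850402 cytosines were common to all libraries with a minimum of 20 reads, against 1107236 with 10. No paired analysis was possible because the replicate numbers follow accession order and pair no libraries.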

Other observations

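The variable promoters and those with wide gaps were chosen after their values were seen. Promoters that varied between libraries within both groups included developmental and imprinted genes. Of 14210 promoters covered in all libraries, 883 (6.21%) had a standard deviation within groups of 10 points or more, with a median of 0.572 points over all promoters. HOXA4 had a standard deviation of 35.4 points and ranged from 9.60% to 97.2%, and HOXA5, its neighbour in the HOXA cluster, had 24.1 points with a range of 33.2% to 95.8%. The imprinted genes PEG3 and ZIM2 had the same values and 21.3 points, and NNAT had 20.9 points with a mean of 51.7%. No list held more variable promoters than the rest after adjustment over 19 lists (imprinted genes 3 of 13, Fisher's exact p = 0.0428, adjusted p = 0.581).

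The promoters with the widest gaps between the groups were mostly at intermediate methylation, which a gap of 20 points or more makes likely by itself. The logistic model gave 22 promoters with a difference of 20 points or more, none of which passed adjustment (adjusted p of at least 0.555). PRSS21, which encodes a serine protease, was at 23.2% ± 25.5 in defective libraries (SD, n = 10) and 56.6% ± 21.7 in non-defective libraries (SD, n = 9; unadjusted exact permutation p = 0.00978). SLC44A2 was at 34.5% and 63.8%. IL2RA, for the alpha chain of the interleukin 2 receptor, was at 59.4% ± 26.4 and 31.5% ± 28.7, and FXYD2 at 53.2% and 25.3%. COX6A2, for a muscle form of a cytochrome c oxidase subunit, was at 64.1% ± 15.9 and 41.1% ± 5.70, with the smallest unadjusted exact permutation p of the 22, 0.000487. Of 100 splits of the libraries, 17 gave 22 or more such promoters and the highest other split gave 71, so chance is not excluded.

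Splits of the libraries were counted for the other tests across the genome. The predictions for them were written after the real counts and before those of the splits were seen. With 0 called tiles and 0 called promoters in the real groups, all 100 splits reach as many whatever the data, so these counts test nothing about chance (highest other 1 tile and 3 promoters). At an unadjusted p under 0.05, 48 splits gave as many tiles as the real 8247 (highest other 12698) and 46 gave as many promoters as the real 1278 (highest other 1824). The excess of tiles higher over tiles lower in defective libraries was 1801, and 74 splits gave as large an excess of either direction (highest other 5974). Chance is not excluded for the counts at an unadjusted p or for the excess.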
